A study of Homo sapiens with 10 samples.

How the data were processed

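Human K562 cells, an established chronic myeloid leukaemia line, were grown for 12 h with 30 µM 4-thiouridine, a nucleoside that is built into newly made RNA. Per the labels' protocols the medium was exchanged every 3 h during this pulse. The cells were then washed and moved to medium with 3 mM uridine and either DMSO, 1 µM JQ1 or 1 µM AZ-5576. JQ1 blocks the bromodomains of the BET proteins, which help RNA polymerase II to be released into elongation. AZ-5576 inhibits CDK9, the kinase of the elongation factor P-TEFb. Cells were taken at 0, 2, 4 and 8 h of the uridine chase, and the 0 h library is shared by the 3 arms. Per the labels' protocols, RNA from fly S2 cells was added at 5% to the purified RNA. Iodoacetamide then modified the 4-thiouridine so that it is read as a T-to-C change, and 3′ end libraries were made (QuantSeq, forward). Since the fly RNA was added in proportion to the purified RNA, values per fly read are relative to the mass of that RNA, not to the number of cells. Growth during the chase dilutes the labelled RNA.

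The authors deposited 3 tables of raw read counts per gene, one for all human reads (total RNA), one for reads named nascent and one for the fly reads. The deposited nascent counts were taken here as reads that carry T-to-C changes, called labelled reads below. The rule by which the authors called a read labelled is not given in the sources used here, nor are the aligner, the counting tool and the annotation. Per the submitters' processing notes, bcl2fastq 2.17.1.14, Trim Galore 0.6.5 and bedtools were used with the human build hg38 and the fly build dm6. No gene had more labelled than total reads in any library. The tables list 59204 human and 17509 fly genes, and 28888 human genes had no read. Symbols were matched for 55381 human identifiers. The other 3823 identifiers held 0.249% of the total reads. Gene positions and classes are those of GENCODE v29 (GRCh38). Genes with near-identical copies, such as processed pseudogenes, globin pairs, histones and small nuclear RNAs, are uncertain, because reads could be split between the copies.

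Total reads per library ran from 10293371 to 16008906, labelled reads from 2031796 to 3868420 and fly reads from 1208073 to 2366155. Each condition has 1 library (n = 1), so no difference has a replicate check. The p-values below measure the scatter of the libraries about the time-course model, which mixes biology, handling and misfit of the model. Intervals on counts and on shares are exact (Clopper-Pearson, 95%) and cover counting error only, since reads of these libraries without molecular identifiers are not independent molecules.

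Counts were fitted with edgeR's quasi-likelihood test (edgeR 4.0.16 in R 4.3.3), with the fly read total of each library as its scale and genes with a mean count of at least 20. This left 11797 genes for total RNA and 8817 for labelled RNA. Total RNA under each inhibitor was compared with DMSO by a model with one level per time point and one term per inhibitor, which leaves 4 residual degrees of freedom and averages the difference over 2, 4 and 8 h. Loss of labelled RNA was fitted as a straight line in log2 counts over hours, with a common 0 h level and one slope per arm, and the slopes were compared between arms. That model leaves 6 residual degrees of freedom. The half-life is the inverse of a slope below 0. The change of total RNA over time in DMSO used the same slope model. Adjusted p-values are Benjamini-Hochberg values with a threshold of 0.05, and standard errors (SE) are those implied by the quasi-likelihood F. Ratios between 2 libraries used a pseudocount of 0.5. The common biological coefficient of variation was 0.362 in the time-level model of total RNA, 0.205 in its slope model and 0.188 for labelled RNA.

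A total of 22 gene lists were fixed before the data were examined, as were the main designs, the alternatives and the rule for named genes. They cover short-lived immediate-early and feedback regulators, erythroid and leukaemia transcription factors, globins and erythroid products, ribosomal proteins, mitochondrially encoded mRNAs, oxidative phosphorylation, glycolysis, the Pol II elongation and BET machinery, genes known to rise under BET inhibition, apoptosis, G1/S, mitosis, MYC-linked ribosome biogenesis, mRNA decay, the integrated stress response, heat shock, cholesterol synthesis, the proteasome, splicing regulators, numbered ZNF genes, noncoding host RNAs and markers of other cell types. Lists were tested with camera (limma 3.58.1) against all other genes, with a preset correlation of 0.01 between genes and again with an estimated correlation. Members past the threshold were counted over all genes tested and with p-values adjusted over the list alone.

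The named genes are, for each inhibitor, the 8 largest falls and rises of total RNA past the threshold with a mean count of at least 100 and one sign at all 3 times, filled from genes past the threshold with TMM scaling. To these were added the 5 largest loss-rate differences each way with a mean labelled count of at least 50. Further come the 8 shortest and 8 longest half-lives in DMSO with a mean labelled count of at least 100 and an SE well below the slope (slope more than 3 times the SE), and the 5 largest rises and falls over time in DMSO with a mean count of at least 100. A panel of leukaemia, erythroid and reference genes and the 2 to 4 most abundant members of each list complete the rule. Some genes that the rule names are not reported here, while the counts over all genes and over lists include them.

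Each fit was tested on simulated counts with 200 changed genes, 50 per size. For AZ-5576 against DMSO, edgeR recovered 72% of genes lowered by 2 log2 units, 10% of those lowered by 1, 16% of those raised by 1 and 80% of those raised by 2, with 1 false call among 90. For the loss-rate difference AZ-5576 minus DMSO it recovered 74% at −0.2 log2 per hour, 16% at −0.1, 30% at 0.1 and 90% at 0.2, with 2 false calls among 107. The list test called 0 of 22 lists with no shift, and called the list lowered by 1 under the preset and the estimated correlation. The simulated genes varied independently, so this does not show how either setting performs where genes vary together. In the data the estimate for AZ-5576 against DMSO was 0.494 for the immediate-early list and 0.722 for the erythroid factors. Such estimates rest on few residual degrees of freedom and include misfit of the model.

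Alternatives covered TMM scaling, a median ratio of the fly genes, DESeq2 1.42.0, limma-trend, other count filters, each time point or library left out, only the arms compared, and slopes in place of time levels. For labelled RNA they also covered the labelled share of each gene and TMM factors of the total counts. After the data were examined, a subtraction of false labelled calls and a covariate from the fly genes were added. The covariate is the first principal component of 2069 fly genes with a mean count of at least 100. It held 61.3% of their variance although the same fly RNA was meant for every library. The median log2 deviation of its 20 leading fly genes was −1.33 at 0 h, −0.66, −0.21 and 0.80 at 2, 4 and 8 h in DMSO, −2.33 in the AZ-5576 2 h library and between 0.68 and 0.91 in the other 5 libraries. The fly totals and the median ratio of the fly genes differed by at most 0.06 log2. The same edgeR tests on 4980 fly genes called 0 genes in each of the 3 comparisons between arms and over time in DMSO, with 103 genes at an unadjusted p under 0.05 for AZ-5576 against DMSO, 173 for JQ1 against DMSO, 212 for AZ-5576 against JQ1 and 249 over time in DMSO. Another split shows in a few ribosomal protein pseudogenes. RPS24P6 had 10468 to 15016 reads in 6 libraries and 422 to 635 in the DMSO 4 h library and the 3 libraries of 8 h, a grouping that the labels do not give. In the model with time levels, a term for these 4 libraries is the same as leaving out the DMSO 4 h library.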

Results

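Total and labelled RNA were read in 10 K562 libraries, 1 at 0 h of the chase and 1 at each of 2, 4 and 8 h in DMSO, JQ1 and AZ-5576. Total counts in the order of time were 12099803 at 0 h, 11644394, 12130418 and 16008906 in DMSO, 12685641, 14177094 and 13859882 in JQ1, and 12266820, 10293371 and 12729708 in AZ-5576. The corresponding labelled counts were 3868420 at 0 h, 3389285, 2538060 and 2113477 in DMSO, 3690627, 3346476 and 2031796 in JQ1, and 3744645, 2953490 and 3247873 in AZ-5576. The labelled share of all reads was 32.0% at 0 h (exact 95% interval 31.9% to 32.0%). By 8 h it was 13.2% in DMSO, 14.7% in JQ1 and 25.5% in AZ-5576. Human reads per fly read were 8.18 at 0 h. They were 9.64, 8.87 and 9.08 at 2, 4 and 8 h in DMSO, 7.91, 7.77 and 7.94 in JQ1, and 9.01, 7.01 and 5.38 in AZ-5576. The series title concerns RNA decay and the response of leukaemia to transcriptional perturbation, so the comparisons ask which RNAs moved under each inhibitor and how fast labelled RNA was lost.

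**Figure D1:**
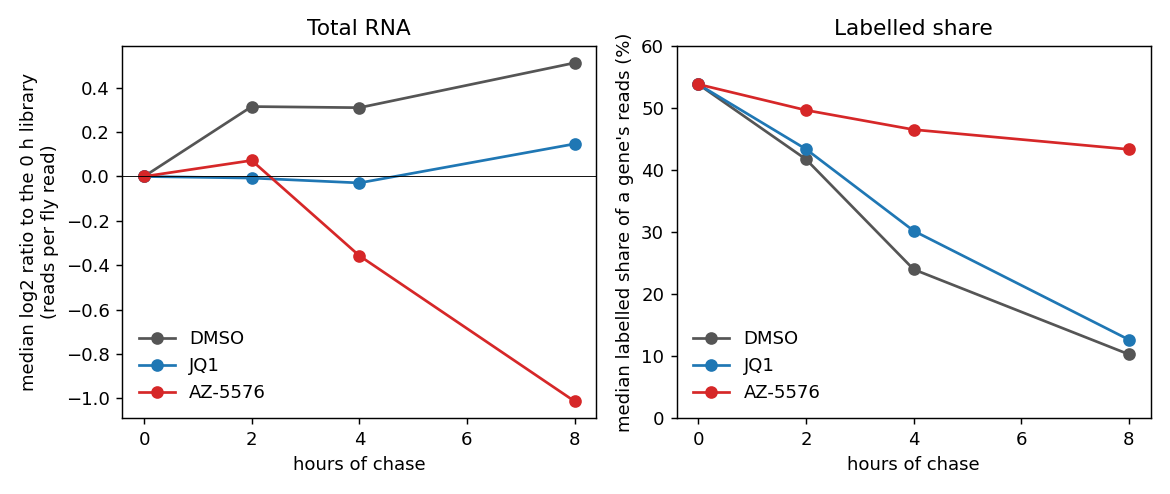
Left, the median over genes of the log2 ratio of total RNA to the 0 h library, per fly read, against hours of chase; right, the median labelled share of a gene's reads in percent. Each point is 1 library; at 8 h the AZ-5576 library sits at −1.01 on the left and at 43.3% on the right, against 0.51 and 10.3% in DMSO.

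Under the CDK9 inhibitor AZ-5576, the median of immediate-early and feedback regulators was the lowest of the 22 lists, with 27 of 49 members called, while the medians of ribosomal protein and oxidative phosphorylation genes stayed near the DMSO level. No list passed with an estimated correlation (adjusted p = 0.716 for the regulators). Over 2, 4 and 8 h, SOCS3, a feedback inhibitor of cytokine signalling, fell by 5.62 log2 units (SE 0.58, adjusted p = 0.00742) and NFKBIA, the inhibitor of NF-κB, fell by 4.60 (SE 0.51, adjusted p = 0.00995). JUNB, a subunit of the AP-1 transcription factor, fell by 3.64 (SE 0.44, adjusted p = 0.00995), and MCL1, an anti-apoptotic BCL2 relative, fell by 2.48 (SE 0.48, adjusted p = 0.0419). All 4 were below DMSO at every time, and at 8 h MCL1 was at 6.49% of DMSO (exact 95% interval 5.82% to 7.21%). MYC, the driver of cell growth, was at 53.8% of DMSO at 2 h, 3.36% at 4 h and 0.833% at 8 h (0.454% to 1.40%). Its mean difference of −3.76 (SE 1.04) had an adjusted p of 0.0556.

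Of the 11797 genes tested by edgeR, 291 passed the threshold, 281 lower and 10 higher under AZ-5576, and 5198 had an unadjusted p under 0.05. Against the 0 h library the median log2 ratio of all genes was 0.07, −0.36 and −1.01 at 2, 4 and 8 h in AZ-5576. In DMSO it was 0.32, 0.31 and 0.51, so ratios to DMSO also hold a rise in DMSO. The median log2 ratio of all genes to DMSO was −0.25 at 2 h, −0.67 at 4 h and −1.63 at 8 h, and averaged over the times it was −0.82 in the model. TMM scaling, which centres each library on its own genes, moved that median to −0.08 and called 302 genes, 274 of them lower, of which 194 were among the 291. Ratios in this text are therefore per fly read unless TMM is named. The number of calls depended on single libraries. It was 1492 without the DMSO 2 h library, 1 without DMSO 4 h, 1 without DMSO 8 h, 6842 without AZ-5576 2 h, 2 without AZ-5576 4 h and 1688 without AZ-5576 8 h. Without all libraries of 2, 4 or 8 h it was 5716, 6 or 1458. The AZ-5576 2 h and 0 h libraries also stood apart in their fly genes, and with the fly component as a covariate, an alternative chosen after seeing the data, 3943 genes passed, 3912 of them lower, among them all 291. With slopes over hours in place of time levels, 8709 genes passed, 8643 of them lower and again including all 291. The model with time levels holds 1 difference for all times, so a difference that grew over the hours counts as scatter in it. Its biological coefficient of variation was 0.362, against 0.205 with slopes.

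Other genes with large falls were ZNF296, a zinc finger protein, at −3.97, the growth factor response gene IER3 at −3.76, the immediate-early gene CSRNP1 at −3.74, IER5 at −3.73, OSR2 at −3.70 and the noncoding RNA ENSG00000264066 at −4.82. Their adjusted p ran from 0.00995 to 0.0485, and each was below DMSO at all 3 times. Of the fixed panel, IER2 fell by 2.39, the kinase gene PIM1 by 2.52 and ID1, an inhibitor of differentiation factors, by 2.55, with adjusted p of 0.0105, 0.0465 and 0.031. RNVU1-25, a variant U1 small nuclear RNA whose reads could come from near-identical copies, rose by 3.30 (SE 0.46, adjusted p = 0.0134) and was the rise named by the rule. With TMM scaling alone the rule added ENSG00000273199 at 2.59, ENSG00000226499 at 0.90, AMH at 0.35 and MROH6 at 0.35, none of which passed per fly read. SOCS3 (ENSG00000184557) lies on chromosome 17 at 78356778 to 78360077 of GRCh38, minus strand, and MYC (ENSG00000136997) on chromosome 8 at 127735434 to 127741434, plus strand. MCL1 (ENSG00000143384) lies on chromosome 1 at 150574551 to 150579738, minus strand, and NFKBIA (ENSG00000100906) on chromosome 14 at 35401511 to 35404749, minus strand.

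Among 49 measured immediate-early and feedback regulators, 27 fell under AZ-5576 over all genes and 42 fell when adjusted over the list alone. Their median difference was −2.51, and at 8 h their median ratio was −3.94. The list lay below other genes with camera's preset correlation (adjusted p = 1.06e-13; adjusted p = 0.716 with an estimated correlation). Of 302 ZNF genes, which encode mostly zinc finger repressors, 29 fell and 223 fell adjusted over the list alone (median −1.52, adjusted p = 6.98e-12; adjusted p = 0.894 with an estimated correlation). Of 29 erythroid and leukaemia transcription factors, 1 fell, ZBTB7A, a repressor of fetal globin, by 1.45 (SE 0.25, adjusted p = 0.0283), and 12 fell adjusted over the list alone. The median of that list was −1.22, with an adjusted p of 0.0382 under the preset and 0.894 with an estimated correlation. MYB was at −1.84, GATA2 at −2.11, KLF1 at −2.12, NFE2 at −2.04, TAL1 at −1.33, LMO2 at −1.22 and GATA1 at −0.75, none past the threshold in the model with time levels. In the slope model all 29 erythroid factors fell, as did 44 immediate-early regulators and 285 ZNF genes, beside 8643 of all 11797 genes.

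Of 38 genes of the Pol II elongation and BET machinery 0 fell over all genes with edgeR, 26 adjusted over the list alone and 36 with slopes (median −1.14). BRD2 was at −1.33, while CDK9 itself was below the count minimum. Of 26 genes of the integrated stress response 4 fell and 16 adjusted over the list alone (median −1.05). Of 75 mRNA decay genes 4 fell and 40 adjusted over the list alone (median −0.89). The preset p-values of these 3 lists were 0.0315, 0.0331 and 0.0309, each with an adjusted p of 0.894 with an estimated correlation. Of 40 MYC-linked ribosome biogenesis genes 1 fell and 32 adjusted over the list alone (median −1.02), with NCL at −0.77 and NPM1 at −0.55. Of 38 splicing regulators 3 and 24 fell in the same 2 counts (median −0.73), and of 19 BCL2 family and apoptosis genes 2 and 7 (median −1.07). For 42 mitosis genes the counts were 0 and 15 (median −0.99), for 40 G1/S genes 0 and 4 (median −0.85), for 18 heat shock genes 0 and 4 (median −0.81), for 22 cholesterol genes 1 and 2 (median −0.35) and for 31 proteasome genes 0 and 0 (median −0.50). For 22 noncoding host RNAs they were 4 and 7 (median −0.51), with SNHG3, the host of small nucleolar RNAs, which fell by 1.75 (SE 0.22, adjusted p = 0.011). None of these last 9 lists passed with the preset correlation. The slope model called far more falls, with 37 of 40 ribosome biogenesis, 37 of 38 splicing, 17 of 19 BCL2 family and 40 of 42 mitosis genes. It also called 37 of 40 G1/S, 16 of 18 heat shock, 13 of 22 cholesterol, 25 of 31 proteasome and 18 of 22 host RNA genes. For the integrated stress response it called 24 of 26 and for mRNA decay 69 of 75.

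Another 7 lists lay above other genes with the preset correlation, with 0 members called by edgeR over all genes and adjusted over the list alone. The 77 ribosomal proteins had a median of −0.05 (adjusted p = 1.62e-19, 0.716 with an estimated correlation) and the 66 oxidative phosphorylation genes −0.11 (adjusted p = 6.70e-10, 0.784 with an estimated correlation). The 11 mitochondrially encoded mRNAs, which another polymerase makes, had a median of 0.12 (adjusted p = 5.96e-08, 0.0875 with an estimated correlation). The 38 globins and erythroid products had −0.29 (adjusted p = 3.01e-05, 0.865 with an estimated correlation), with the fetal globin HBG2 at 0.06 and the embryonic globin HBZ at 0.14. The 19 glycolysis genes had −0.17 (adjusted p = 0.00288, 0.894 with an estimated correlation), with GAPDH at −0.14. The 10 genes known to rise under BET inhibition had −0.23 (adjusted p = 0.0211, 0.894 with an estimated correlation). The 9 markers of other cell types had −0.20 (adjusted p = 0.00749, 0.716 with an estimated correlation). Slopes called 16 falls among the globins and erythroid products, 19 in oxidative phosphorylation, 6 in glycolysis, 3 in the BET list and 1 each in the ribosomal and the mitochondrial list. ACTB was at −0.16, EEF1A1 at −0.29, RPLP0 at −0.04 and TFRC, the transferrin receptor, at −1.47, none past the threshold.

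**Figure D2:**
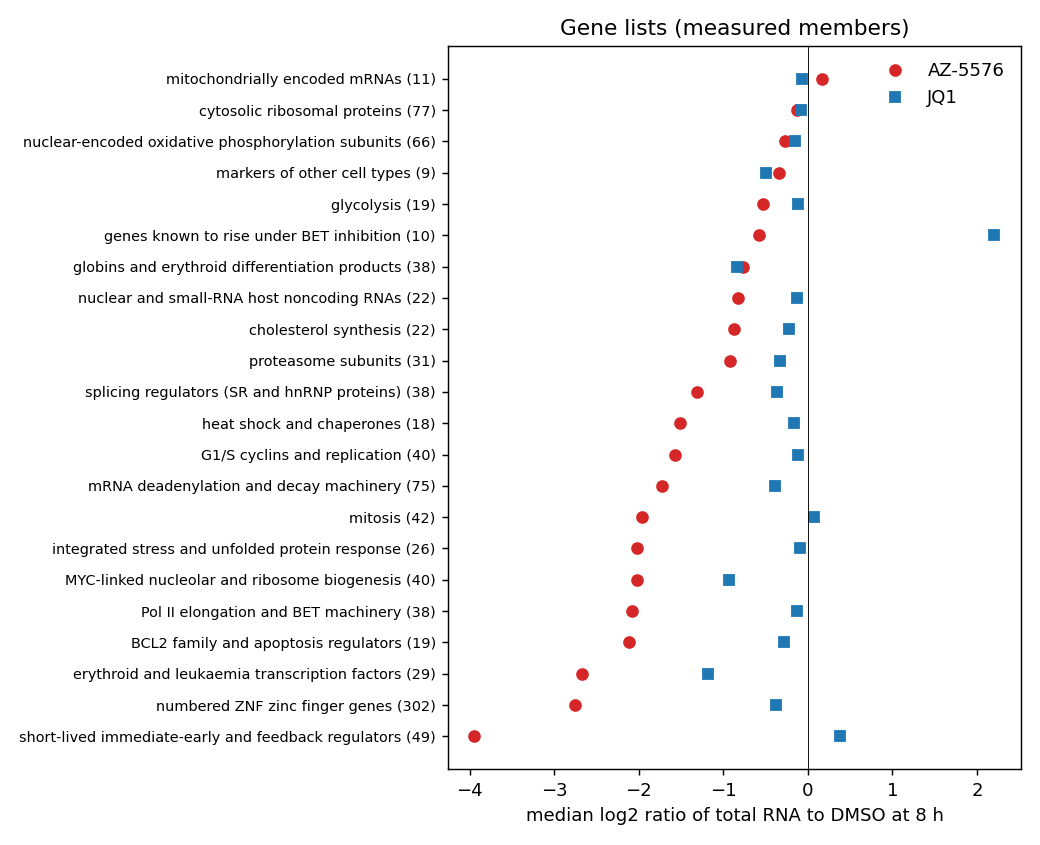
Median log2 ratio of total RNA to DMSO at 8 h, per fly read, over the measured members of each gene list, whose number stands in parentheses. Circles are AZ-5576 and squares JQ1, 1 library each; the immediate-early list sits at −3.94 under AZ-5576 and 0.38 under JQ1, and the list known to rise under BET inhibition at −0.57 and 2.21.

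Under the BET inhibitor JQ1, 5 lists lay apart from other genes in total RNA with camera's preset correlation and 0 with an estimated one. EdgeR called 0 genes over all genes, with 1081 at an unadjusted p under 0.05, while DESeq2 called 71, limma-trend 0 and slopes over hours 2126. Fitted on the DMSO and JQ1 arms alone, edgeR called 2639 genes, 2440 of them lower. The scatter in the fit of all arms also holds the AZ-5576 arm, whose median ratio to DMSO moved from −0.25 at 2 h to −1.63 at 8 h. The 0 calls, and the SE and adjusted p of single genes below, therefore do not show that JQ1 left total RNA unchanged. All 10 measured genes known to rise under BET inhibition were above DMSO, with a median of 1.51, and 7 rose adjusted over the list alone. HEXIM1, the inhibitor of P-TEFb, was at 1.58 (SE 0.61, adjusted p = 0.533), and its JQ1 library at 8 h had 3.97 times the DMSO level (exact 95% interval 3.70 to 4.26). The histone genes H2AC6, H2BC11 and H1-2 were at 1.26, 0.84 and 0.53. Of 29 erythroid and leukaemia transcription factors, 28 were below DMSO, with a median of −1.04 and 0 past the threshold over all genes or adjusted over the list alone. KLF1 and NFE2, activators of globin genes, were at −2.22 and −2.21, MYB at −1.71, LMO2 at −1.36, GATA1 at −1.32, GATA2 at −1.06 and TAL1 at −1.05.

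With camera's preset correlation the BET list lay above other genes (adjusted p = 2.27e-18, 0.693 with an estimated correlation) and the erythroid list below them (adjusted p = 2.69e-05, 0.918 with an estimated correlation). MYC-linked ribosome biogenesis genes lay below other genes (median −0.61, adjusted p = 0.00334, 0.918 with an estimated correlation), as did ZNF genes (median −0.52, adjusted p = 0.0173, 0.918 with an estimated correlation, 1 fall adjusted over the list alone). The immediate-early list lay above other genes (median 0.06, adjusted p = 4.16e-08, 0.918 with an estimated correlation), with 2 rises and 1 fall adjusted over the list alone. MYC was at −1.88 (SE 0.86, adjusted p = 0.538) and at 31.5% of DMSO at 8 h. Its RNA rose over time in DMSO, as given below, so this ratio need not be a fall from 0 h. BCL2L1, which protects erythroid cells from apoptosis, was at −1.33, PIM1 at −1.56, MCL1 at 0.31 and BRD2 at 0.61. GADD45B, a stress-induced gene, was at 3.35 (SE 0.48, adjusted p = 0.26), with 378, 482 and 364 reads in JQ1 against 32, 15 and 63 in DMSO. The neuronal tubulin TUBB3 was at 2.51 and LSMEM1 at 1.83. These 3 genes were named from TMM scaling, which called 4 genes, all of them higher.

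The other lists had medians between −0.39 and −0.15 and did not pass with the preset. In order they were globins and erythroid products at −0.39 (1 fall adjusted over the list alone), decay genes at −0.39, markers of other cell types at −0.33 (1 rise adjusted over the list alone), BCL2 family at −0.30, proteasome at −0.30, splicing regulators at −0.27, mitosis at −0.20, cholesterol synthesis at −0.20, G1/S at −0.19, glycolysis at −0.18, mitochondrially encoded mRNAs at −0.18, oxidative phosphorylation at −0.17, heat shock at −0.17, ribosomal proteins at −0.16, integrated stress response at −0.16, Pol II machinery at −0.15 and host RNAs at −0.15. The median of all genes was −0.31 in the model and 0.01 with TMM scaling. Against the 0 h library, per fly read, it was −0.01, −0.03 and 0.15 at 2, 4 and 8 h in JQ1. In DMSO it was 0.32, 0.31 and 0.51, so the gap was a rise in DMSO more than a fall under JQ1. Without the 2, 4 or 8 h libraries 225, 1 or 19 genes passed, and of the 2126 with slopes 1915 were lower. With slopes all 10 genes of the BET list rose, 18 of the 29 erythroid factors fell, as did 27 ribosome biogenesis genes and 66 ZNF genes, and of the immediate-early list 7 rose and 9 fell.

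**Figure D3:**
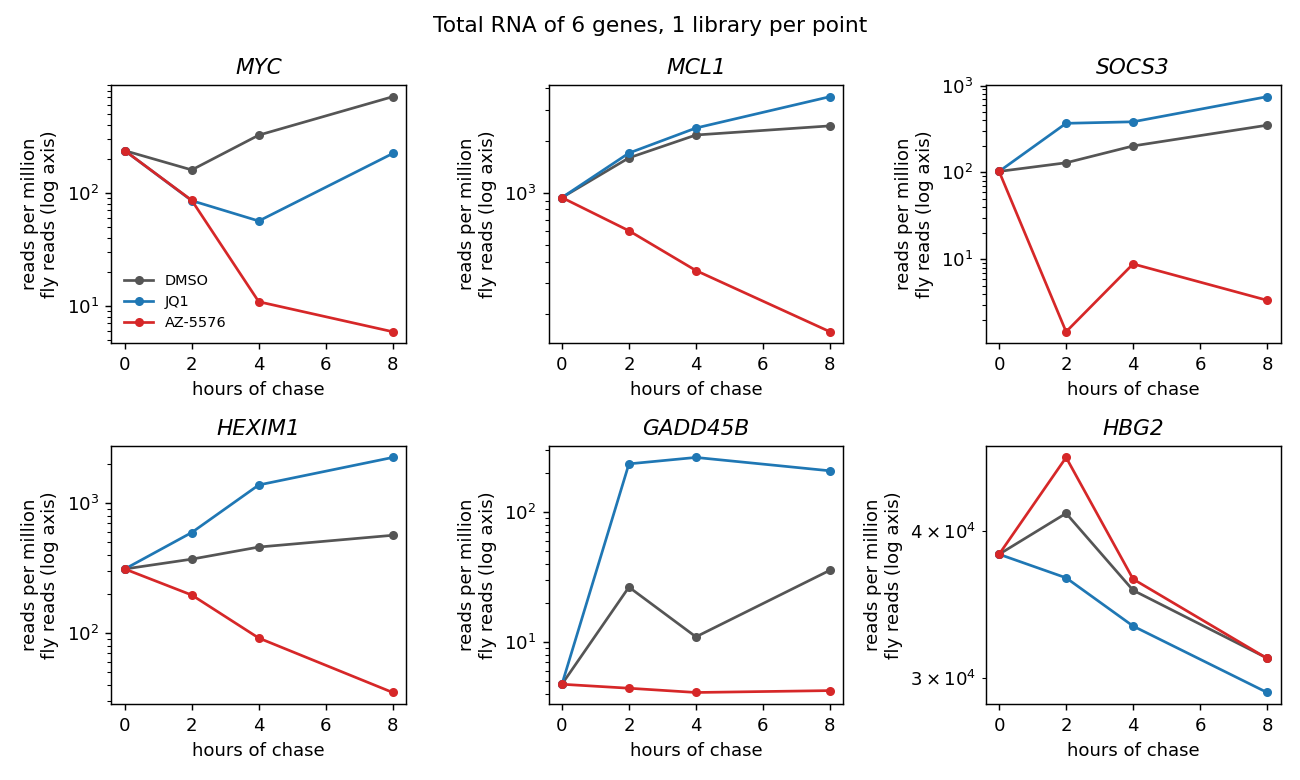
Reads of 6 genes relative to fly reads (logarithmic axis, unit on the axis) against hours of chase in DMSO, JQ1 and AZ-5576, with 1 library per point and a common 0 h library. MYC sits at 0.833% of DMSO in AZ-5576 at 8 h, HEXIM1 sits at 3.97 times DMSO in JQ1 at 8 h, and the globin HBG2 keeps within a narrow range in all arms.

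Compared directly, AZ-5576 lay below JQ1 for 22 of 49 immediate-early and feedback regulators, a list that did not pass with an estimated correlation (adjusted p = 0.646). SOCS3 differed by −6.82 log2 units (SE 0.60, adjusted p = 0.00164), GADD45B by −5.82 (SE 0.55, adjusted p = 0.00164), IER5 by −5.22 (SE 0.85, adjusted p = 0.022) and EGR1, an immediate-early transcription factor, by −4.32 (SE 0.58, adjusted p = 0.0102). HEXIM1 differed by −3.68 (SE 0.70, adjusted p = 0.0397) and MCL1 by −2.78 (SE 0.49, adjusted p = 0.0317). MYC differed by −1.88 (SE 0.97, adjusted p = 0.296), and for KLF1 and NFE2 the inhibitors lay close, at 0.11 and 0.16 with SE of 0.66 and 0.63. HEXIM1 (ENSG00000186834) lies on chromosome 17 at 45148502 to 45152101, plus strand, and GADD45B (ENSG00000099860) on chromosome 19 at 2476122 to 2478259, plus strand.

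The direct comparison passed 140 genes with edgeR, 138 of them lower under AZ-5576, with 2389 at an unadjusted p under 0.05 and a median of −0.46 over all genes. Of 49 immediate-early regulators, 22 were lower and 40 adjusted over the list alone (median −2.55, adjusted p = 1.40e-22, 0.646 with an estimated correlation). Of the 10 genes of the BET list 1 was lower and 9 adjusted over the list alone (median −1.65, adjusted p = 0.00032, 0.748 with an estimated correlation). Of ZNF genes 9 were lower and 39 adjusted over the list alone (median −0.99), of integrated stress genes 4 and 12 (median −0.75), and of Pol II machinery genes 1 and 12 (median −0.88). The mitochondrially encoded mRNAs lay above (median 0.28, 3 adjusted over the list alone, adjusted p = 1.94e-06, 0.137 with an estimated correlation), and the erythroid factors had a median of −0.21 and 0 calls. TMM scaling moved the median of all genes to −0.03 and called 608 genes, 569 of them lower. The count was 15 without the JQ1 4 h library, 59 without JQ1 8 h, 3746 without AZ-5576 2 h, 7 without AZ-5576 4 h and 371 without AZ-5576 8 h. It was 3045, 23 or 347 without the 2, 4 or 8 h libraries, 1117 with the fly covariate chosen after seeing the data and 6590 with slopes over hours.

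In DMSO, labelled RNA of immediate-early, erythroid factor and ZNF genes was lost fast by their medians and that of ribosomal protein and oxidative phosphorylation genes slowly, but no list passed with an estimated correlation (adjusted p from 0.179 to 0.956). The median half-life over 8817 genes was 4.49 h, with quartiles at 3.07 and 7.10 h. By the median, labelled RNA had not fallen at 2 h, with log2 ratios to 0 h of 0.09, −0.60 and −1.54 at 2, 4 and 8 h in DMSO. At 2 h the ratio was 0.02 in AZ-5576 and −0.21 in JQ1. The half-lives come from 1 straight line from 0 h, which does not describe these first 2 h in DMSO. Without the 0 h library the median half-life was 4.06 h. SUV39H1, a histone H3K9 methyltransferase, had 1.22 h, the SMN complex gene GEMIN4 1.25 h, the chaperone DNAJB1 1.29 h, TMEM223 1.30 h, the pseudouridine synthase PUS3 1.38 h and RRS1, a ribosome assembly factor, 1.40 h. MTND1P23, a nuclear copy of a mitochondrial gene whose reads could come from mitochondria, had 1.32 h and MT-CYB 1.40 h. The longest half-lives named were 12.0 h for HBG2, 11.8 h for RPL19, 11.7 h for RPS2, 11.6 h for NACA, 11.4 h for COX4I1 and 11.3 h for RPL23A and HDGF. HBG2 and HBG1 are near-identical, so the value of each is uncertain. Median half-lives by list were 1.52 h for mitochondrially encoded mRNAs, 2.22 h for immediate-early regulators, 2.30 h for erythroid factors and 2.43 h for ZNF genes. They were 3.83 h for cholesterol synthesis and 4.63 h for the Pol II machinery, 7.68 h for globins and erythroid products, 7.70 h for glycolysis, 8.54 h for the proteasome, 11.2 h for oxidative phosphorylation and 13.6 h for ribosomal proteins. The slope below 0 passed the edgeR threshold in 7787 genes. A slope of 0 or above was found in 112 genes, and in 4 genes the rise passed the threshold. The half-lives hold per fly read and include dilution by growth. With TMM scaling the slope of the longest-lived genes turned upward, at 0.13 log2 per hour for HBG2, and the median half-life was 87.2 h. Without the 8 h libraries the median was 5.95 h.

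Between arms, labelled RNA of 11 of 32 immediate-early regulators was lost faster under AZ-5576 than in DMSO, but the list did not pass with an estimated correlation (adjusted p = 0.365), and the counts of slower and faster calls depended on the 8 h libraries. The fitted half-life of MYC was 2.76 h in DMSO and 1.10 h under AZ-5576, a slope difference of −0.55 log2 per hour (SE 0.08, adjusted p = 3.58e-08). DDIT4, an inhibitor of mTOR signalling, differed by −0.57 (SE 0.10, adjusted p = 1.17e-05), IER5 by −0.47 (SE 0.05, adjusted p = 1.83e-14), the cytokine inhibitor CISH by −0.46 and the pseudouridine synthase gene RPUSD2 by −0.36. MYC, DDIT4 and CISH had 0 labelled reads in AZ-5576 at 8 h, a value that enters their fits. FAM229A, whose half-life was 1.74 h in DMSO and 8.17 h under AZ-5576, differed by 0.45 (SE 0.07, adjusted p = 2.19e-08), REV3L, a subunit of DNA polymerase zeta, by 0.34, SUV39H1 by 0.32, the pseudogene LRRFIP1P1 by 0.30 and ZNF408 by 0.29. IER5 (ENSG00000162783) lies on chromosome 1 at 181088712 to 181092899, plus strand, DDIT4 (ENSG00000168209) on chromosome 10 at 72273920 to 72276036, plus strand, and FAM229A (ENSG00000225828) on chromosome 1 at 32361270 to 32364278, minus strand.

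EdgeR called 419 of 8817 genes, 311 lost more slowly and 108 faster under AZ-5576, with 1525 at an unadjusted p under 0.05. The median half-life was 5.39 h under AZ-5576, with quartiles at 3.65 and 8.27 h. The median slope difference was 0.03 log2 per hour. Of 32 immediate-early regulators, 11 were lost faster and 3 more slowly, and 16 and 3 adjusted over the list alone. Their median difference was −0.13 (adjusted p = 1.07e-12, 0.365 with an estimated correlation), and their median half-life was 2.22 h in DMSO and 1.68 h under AZ-5576. Of 38 splicing regulators 6 were lost more slowly and 0 faster, of 70 decay genes 7 and 1, and of 166 ZNF genes 9 and 4. Of 77 ribosomal protein genes edgeR called 0. With TMM scaling 567 genes passed, but 236 more slowly and 331 faster, and 325 of them were among the 419, and with TMM factors of the total counts 7726 were slower and 27 faster. The count was 639 without the DMSO 2 h library, 272 without DMSO 4 h, 35 without DMSO 8 h, 239 without AZ-5576 4 h and 28 without AZ-5576 8 h. It was 768 without the 0 h library, 35 or 15 without the 4 or 8 h libraries, and 3 with a model that had one level per time. More genes were faster than slower without DMSO 8 h (2 slower and 33 faster), without AZ-5576 8 h (6 and 22), without all 8 h libraries (0 and 15) and with one level per time (0 and 3). The median slope difference over all genes was 0.00397 without DMSO 8 h, 0.0422 without AZ-5576 8 h and 0.0169 without all 8 h libraries, against 0.0301. Within each gene, the labelled share fell more slowly under AZ-5576 even for MYC, at 0.39 log2 per hour, for DDIT4 at 0.39, IER5 at 0.43, CISH at 0.30 and RPUSD2 at 0.57; the total RNA of these genes was lower as well.

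Under JQ1 few genes were lost at another rate than in DMSO by the test, with EGR1 and IER5 among the slower ones and MYB and HEMGN among the faster. Only 1 list, the genes known to rise under BET inhibition, passed with camera's preset correlation, and 0 with an estimated one. The immediate-early and erythroid factor lists did not pass. EGR1 differed from DMSO by 0.46 log2 per hour (SE 0.07, adjusted p = 2.33e-07), TUBB3 by 0.44 (SE 0.06, adjusted p = 3.17e-08), IER5 by 0.30 (SE 0.04, adjusted p = 1.13e-09), HEXIM1 by 0.26 (SE 0.04, adjusted p = 9.72e-06) and the kinase gene STK17B by 0.27. Lost faster were TARS2, a mitochondrial threonyl-tRNA synthetase, by −0.44, ZNF689 by −0.39, the ribosome rescue factor PELO by −0.33, the erythroid nuclear protein gene HEMGN by −0.32, ADO by −0.28 and MYB by −0.16 (SE 0.04, adjusted p = 0.00667). The half-life of HEMGN was 7.37 h in DMSO and 2.21 h in JQ1. The labelled reads of TUBB3 were 22, 18 and 21 in DMSO and 60, 140 and 170 in JQ1. Its labelled RNA thus rose in JQ1, by 0.27 log2 per hour (SE 0.05, edgeR adjusted p = 1.02e-06), which slower loss alone cannot give. Mean log2 ratios of total RNA to DMSO under JQ1 were 1.47 for EGR1, 2.41 for TUBB3, 1.47 for IER5 and 1.42 for HEXIM1. For such genes, label entering new RNA and false labelled calls were not told apart from slower loss.

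EdgeR called 59 genes between JQ1 and DMSO, 28 lost more slowly and 31 faster, with 657 at an unadjusted p under 0.05 and a median half-life of 4.27 h in JQ1. Of 8 genes of the BET list 1 was lost more slowly and 5 adjusted over the list alone (median 0.11, adjusted p = 6.99e-09, 0.377 with an estimated correlation), with a median half-life of 3.90 h in DMSO and 7.78 h in JQ1. Total RNA of this list lay above DMSO under JQ1, so label entering new RNA could also lengthen its fitted half-life. Of 32 immediate-early regulators 5 were lost more slowly and 1 faster, and 10 and 4 adjusted over the list alone. TMM scaling called 91 genes, 57 more slowly and 34 faster, and TMM factors of the total counts 139 and 7. The count was 87 without the 0 h library, 10 without the DMSO 8 h library, 23 without JQ1 4 h, 15 without JQ1 8 h, 7 or 2 without the 4 or 8 h libraries, and 4 with one level per time. On the labelled share of the gene, ZNF689, HEMGN, ADO and TUBB3 changed sign.

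Directly compared, IER5 was lost faster under AZ-5576 than under JQ1 by −0.77 log2 per hour (SE 0.05, adjusted p = 6.63e-47), EGR1 by −0.79 (SE 0.09, adjusted p = 5.46e-17), DDIT4 by −0.55, the phosphatase regulator PPP1R10 by −0.52 and the antiproliferative gene BTG1 by −0.49. TARS2 was lost more slowly by 0.54 (SE 0.09, adjusted p = 1.91e-06), ZNF689 by 0.43, LRRFIP1P1 by 0.33, ZSCAN26 by 0.32 and FAM219B by 0.29. Of 32 immediate-early regulators 16 were lost faster and 2 more slowly, 17 and 4 adjusted over the list alone (median −0.20, adjusted p = 1.40e-19, 0.14 with an estimated correlation). EdgeR called 490 genes, 399 lost more slowly and 91 faster under AZ-5576, with 2017 at an unadjusted p under 0.05. TMM scaling called 474, 157 more slowly and 317 faster, and TMM factors of the total counts 6945 and 49. The count was 33 without the JQ1 8 h library, 326 without AZ-5576 4 h, 45 without AZ-5576 8 h, 1314 without the 0 h library, 67 or 25 without the 4 or 8 h libraries, and 22 with one level per time. More genes were faster than slower without JQ1 8 h (6 slower and 27 faster), without AZ-5576 8 h (8 and 37), without all 8 h libraries (2 and 23) and with one level per time (2 and 20). The median slope difference over all genes was 0.0444, 0.0576 and 0.0540 in the first 3 of these settings, against 0.0458. On the labelled share of the gene, EGR1, IER5, DDIT4, PPP1R10 and BTG1 changed sign.

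Genes whose labelled RNA was lost fastest in DMSO lay lowest in total RNA under AZ-5576. Of 5 equal groups of genes by half-life, in the one with a median of 2.32 h, total RNA was at −2.29 log2 units of DMSO at 8 h, and in the one at 11.9 h it was at −0.73, while under JQ1 these values were −0.33 and −0.22. MYC and SOCS3 belong to the short end and HBG2 to the long end. Across 8817 genes, Spearman's rho between the loss rate in DMSO and the ratio of total RNA to DMSO was −0.161, −0.410 and −0.440 at 2, 4 and 8 h of AZ-5576, and −0.202, −0.214 and −0.035 under JQ1. The covariances were −0.00907, −0.0412 and −0.0688 for AZ-5576 and −0.00928, −0.0112 and −0.00326 for JQ1. Genes are not independent replicates, so no p-value is given for these 6 relations. Simulated counts that share the DMSO libraries but hold no relation gave −0.022, 0.004 and 0.024 for AZ-5576 and −0.026, 0.006 and 0.021 for JQ1. Labelled and unlabelled reads varied separately in them, so they do not bound what scatter shared by both kinds of read could give. For another relation, given below, such shared scatter alone gave 0.645 in simulation. With the loss rate taken from the JQ1 arm, the values for AZ-5576 were −0.201, −0.445 and −0.495, and with that from the AZ-5576 arm those for JQ1 were −0.239, −0.338 and −0.068. Without the 8 h libraries in the loss rate, rho was −0.0686, −0.254 and −0.311 at 2, 4 and 8 h of AZ-5576 and −0.140, −0.0897 and −0.0437 under JQ1. With minus the labelled share at 2 h in place of the loss rate it was 0.094, 0.0979 and 0.140 for AZ-5576 and, at 4 h of JQ1, 0.102, with the sign turned. At 0 h the median share was 65.2% in the short-lived immediate-early list and 15.7% in the long-lived ribosomal protein list. In the short-lived mitochondrial list it was 10.2%. A low share thus need not mean fast loss, so the turned sign does not test the relation.

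**Figure D4:**
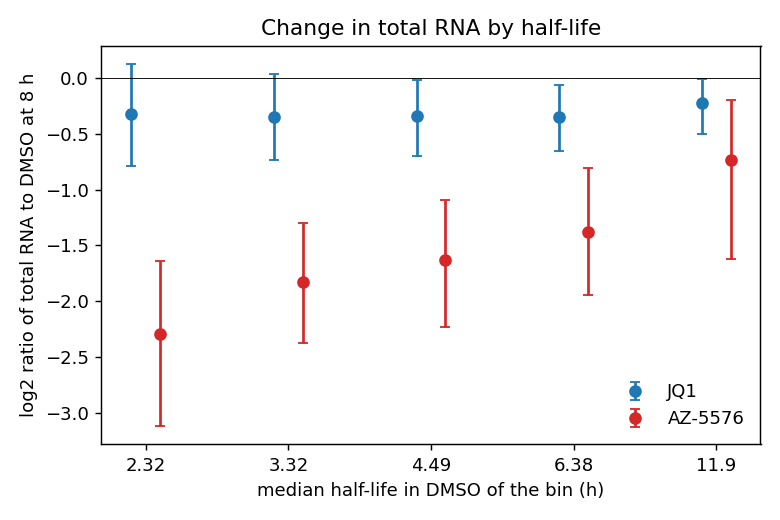
Log2 ratio of total RNA to DMSO at 8 h, per fly read, in 5 groups of genes ordered by half-life in DMSO, placed at each group's median half-life in hours. Points are medians over genes and bars reach from the lower to the upper quartile of genes, in 1 library per inhibitor; AZ-5576 runs from −2.29 to −0.73 and JQ1 from −0.33 to −0.22.

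During the chase in DMSO itself, 27 of 42 mitosis genes, 18 of 38 Pol II machinery genes and 2887 of all 11797 genes rose, and 6 of 22 sterol genes fell, but no list passed with an estimated correlation (adjusted p from 0.634 to 0.913). PLK1, a mitotic kinase, rose by 0.26 log2 units per hour (SE 0.04, adjusted p = 2.94e-05), TAF1, the largest TFIID subunit, by 0.37 (SE 0.05, adjusted p = 2.80e-05), the Pumilio-family gene PUM3 by 0.38, TMEM63B by 0.37, TMEM87B by 0.40 and MYC by 0.29 (SE 0.06, adjusted p = 0.00154). FOSB, an AP-1 subunit, changed by −0.51 per hour (SE 0.19, adjusted p = 0.0487), with 2 reads at 0 h and 682, 155 and 31 after, so that its slope is not a steady fall, and without the 8 h libraries the slope was 0.08. The growth factor gene FGF18 fell by 0.62 and the sterol synthesis genes FDPS, ACAT2 and EBP changed by −0.14, −0.12 and −0.11. The pseudogenes RPL38P5 at 0.65, RPS24P6 at −0.92, RPL35AP33 at −0.39 and RPL31P31 at −0.39 also passed, but 6 libraries against 4 stood apart for RPS24P6, with 12619 reads at 0 h and 424 in DMSO at 8 h. Within DMSO this split sets 0 and 2 h against 4 and 8 h, so in the slope models it cannot be told apart from time. TAF1 (ENSG00000147133) lies on chromosome X at 71366239 to 71532374, plus strand.

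EdgeR called 3333 of 11797 genes over time in DMSO, 2887 rising and 446 falling, with 4727 at an unadjusted p under 0.05. Of 42 mitosis genes 27 rose and 0 fell, and 28 and 2 adjusted over the list alone (adjusted p = 0.00194, 0.911 with an estimated correlation). Of 38 Pol II machinery genes 18 rose and 22 adjusted over the list alone (adjusted p = 0.0121, 0.911 with an estimated correlation). Of 49 immediate-early regulators 17 rose and 2 fell, of 29 erythroid factors 10 rose, of 19 BCL2 family genes 8 rose, of 40 G1/S genes 10 rose, of 40 ribosome biogenesis genes 15 rose and 1 fell, of 75 decay genes 20 and 1, and of 302 ZNF genes 60 and 4. Of 22 sterol genes 2 rose and 6 fell, the same counts adjusted over the list alone (adjusted p = 1.19e-05, 0.768 with an estimated correlation). Of 77 ribosomal protein genes 0 rose and 5 fell, and 0 adjusted over the list alone (adjusted p = 2.18e-11, 0.768 with an estimated correlation). Per fly read the median slope was 0.05 log2 units per hour, and with TMM scaling 3835 genes passed, 2012 rising and 1823 falling. The count was 471 without the DMSO 8 h library and 873 without all 8 h libraries.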

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

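Tests chosen only after the result was seen were the comparison of fast and slow genes, the unlabelled reads of the slower genes, the genes chosen without the 2 h libraries, the JQ1 arm with separate libraries and the search for a plateau in DMSO, and the subtraction of false labelled calls was an alternative chosen after seeing the data; the other tests below were written down before their result was seen.

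Total RNA of 140 genes differed between AZ-5576 and JQ1, and 66 of these had opposite ratios to DMSO at all 3 times, which were picked out because the test of the difference passed. Among all genes tested, 353 had opposite ratios at all 3 times, 316 of them lower under AZ-5576 and higher under JQ1 and 37 the other way. SOCS3, with mean log2 ratios of −5.73 under AZ-5576 and 1.17 under JQ1, GADD45B (−2.29 and 3.40) and HEXIM1 (−2.41 and 1.42) were among the 66. Labelled RNA of 490 genes was lost at a different rate in AZ-5576 and JQ1, picked out for the same reason. Of these, 399 were lost more slowly and 91 faster under AZ-5576, against 6 and 27 without JQ1 8 h, 8 and 37 without AZ-5576 8 h, and 2 and 23 without all 8 h libraries, while the median slope difference over all genes stayed above 0, at 0.0458 and in these settings 0.0444, 0.0576 and 0.0540. Across the 8817 genes measured for both, the mean log2 ratios under the inhibitors had a Spearman's rho of 0.338, against 0.479 in simulated counts that share the DMSO libraries and hold no relation. The covariance was 0.0783 against 0.0572 simulated. The simulated scatter of unlabelled reads was that of the model with time levels, which includes its misfit. These simulated values therefore do not decide whether the inhibitors moved the same genes.

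Each test was repeated on all 10 splits of its 6 libraries into 3 and 3, which are too few for a share under 0.05. In the splits other than the real one each group mixes both arms, so a difference between arms adds to the scatter. Low counts in them are therefore no measure of chance. For total RNA the real split gave the most genes in 2 tests, 291 for AZ-5576 against DMSO and 140 for AZ-5576 against JQ1, so 1 split gave as many, and the highest other split gave 0 in both. For JQ1 against DMSO all 10 splits gave 0. For loss rates, 1 split, the real one, gave as many genes in each test, with 419 against a highest other of 314 for AZ-5576 minus DMSO, 59 against 27 for JQ1 minus DMSO and 490 against 139 for AZ-5576 minus JQ1.

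Labelled RNA was lost more slowly under AZ-5576 than in DMSO for 311 of 419 called genes, but the called genes were 2 slower and 33 faster without DMSO 8 h, 6 and 22 without AZ-5576 8 h, 0 and 15 without all 8 h libraries, and 0 and 3 with one level per time. False labelled calls at one rate in all libraries need more unlabelled reads under AZ-5576, but over the 311 genes their median log2 ratio at 8 h was −1.93 (294 below 0), which argues against them. One shift shared by all genes, from the spike-in scale or from slower growth, would move fast and slow genes alike, and of 5 equal groups the one lost fastest in JQ1 slowed by 0.0477 log2 per hour more than the one lost slowest (interval 0.0414 to 0.0531, from resampling genes, with no spread between libraries), but by 0.0173 without DMSO 8 h, 0.0311 without AZ-5576 8 h and 0.0113 without all 8 h libraries, so it stays open. The median slope difference was 0.0301, with 0.00397 without DMSO 8 h, 0.0422 without AZ-5576 8 h and 0.0169 without all 8 h libraries, so whether the 8 h libraries alone gave the pattern could not be settled with 1 library each. Slower decay once transcription is blocked stays open as a biological explanation, which cannot be told apart from these 2.

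Another pattern went the opposite way, with 108 genes, among them MYC, IER5 and DDIT4, whose labelled RNA was lost faster under AZ-5576. If label still entered new RNA during the chase and AZ-5576 stopped it, these genes would lose unlabelled RNA early, and at 2 h their unlabelled reads were lower by a further −1.23 log2 units than those of other genes (interval −1.34 to −1.03 from resampling genes, with no spread between libraries; 107 of 108 below 0), and for 101 genes chosen without the 2 h libraries by −1.11, or by −0.78 than genes matched on the AZ-5576 loss rate (interval −0.98 to −0.56). In the JQ1 arm the rho of 0.414 between slope difference and unlabelled reads at 8 h decides nothing, since the 2 share libraries and scatter shared by both kinds of read alone gave 0.645 in simulation. With slopes from 0, 2 and 4 h it was 0.224 (highest of 20 simulations 0.0143, over 8817 genes, which are not independent replicates). A plateau, loss in DMSO that slows after 4 h, was not seen clearly against matched genes, at 0.0171 log2 per hour (interval −0.0568 to 0.0743, from resampling genes). Loss became faster in both sets, by −0.0963 in the 108 genes and −0.113 in the matched ones. The test cannot see label that entered mainly early. The match was not full, with median AZ-5576 slopes of −0.431 for matched genes and −0.574 for the 108, and the 101 genes were matched in the same way. False labelled calls at a rate shared by all genes were argued against, while rates that differ between genes were not tried. Of the 108 genes, 88 still passed after subtraction at a rate of 0.269%, and 61 at a rate of 1%, which left 62 faster calls. Continued labelling is thus a candidate explanation, and a truly faster decay of these mRNAs, which would also lower their unlabelled reads, remains open.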

How the results depend on the processing

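The 14 called of 38 named genes checked kept the direction of their total RNA difference between AZ-5576 and DMSO under the alternatives run, but the counts of called genes moved, and except where the setting itself has fewer genes or libraries the cause was not tested. Among uncalled named genes the sign turned in 1 or more alternatives for GATA1, CCND3, GAPDH, ACTB, EEF1A1, RPLP0, HBG1 and HBZ under AZ-5576, and for HBG1, HBG2, TFRC, GAPDH, ACTB, RPLP0, MCL1 and BRD2 of 28 under JQ1, where none was called by edgeR; TMM scaling turned 6 of each 8. The background subtraction and the fly covariate were chosen after seeing the data. For AZ-5576 against DMSO (291 genes), DESeq2 called 4192, limma-trend 2824, no gene filter 3605, a mean count of at least 100 left 31, only the arms compared gave 1685, slopes 8709, the fly covariate 3943, and the data without 2, 4 or 8 h gave 5716, 6 or 1458. With 1 library left out the count ran from 1 to 6842. For JQ1 against DMSO (0 genes), TMM called 4, DESeq2 71, no filter 212, only the arms 2639, slopes 2126, and without 2, 4 or 8 h 225, 1 or 19; limma-trend, the fly covariate (705 at an unadjusted p under 0.05) and each library left out gave 0. For AZ-5576 against JQ1 (140 genes), TMM called 608, DESeq2 1212, limma-trend 320, no filter 1358, at least 100 reads 36, only the arms 13, slopes 6590, the fly covariate 1117, without 2, 4 or 8 h 3045, 23 or 347, and 1 library left out 7 to 3746. Over time in DMSO (3333 genes) the count was 873 without 8 h and 471 to 3071 with 1 library left out, and FOSB turned to 0.0845 without 8 h.

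For loss rates AZ-5576 minus DMSO (419 genes), TMM factors of the total counts gave 7753, DESeq2 279, limma-trend 649, no filter 251, one level per time 3, the labelled share of the gene 7756, without 0, 4 or 8 h 768, 35 or 15, only the arms 183, and 1 DMSO or inhibitor library left out 28 to 639, with more faster than slower genes without DMSO 8 h (2 slower, 33 faster), AZ-5576 8 h (6, 22) or all 8 h (0, 15). For JQ1 minus DMSO (59 genes) they gave TMM 91, TMM factors of total counts 146, DESeq2 37, limma-trend 102, at least 100 reads 34, one level per time 4, the labelled share 526, without 4 or 8 h 7 or 2, a background of 1% subtracted 33, without 0 h 87, and 1 DMSO or inhibitor library left out 10 to 49. For AZ-5576 minus JQ1 (490 genes) they gave TMM factors of total counts 6994, limma-trend 829, no filter 306, one level per time 22, the labelled share 7044, without 0, 4 or 8 h 1314, 67 or 25, and 1 JQ1 or AZ-5576 library left out 33 to 390, with more faster than slower genes without JQ1 8 h (6 slower, 27 faster), AZ-5576 8 h (8, 37) or all 8 h (2, 23). Slower and faster genes were 7726 and 27, 139 and 7, and 6945 and 49 in the 3 comparisons with TMM factors of total counts, and 7754 and 2, 507 and 19, and 7043 and 1 on the labelled share. The fly covariate left the loss rates within 1.5 times, with 356, 40 and 371 genes, 354, 39 and 353 of them shared. On the labelled share of the gene, which falls more slowly where total RNA falls, slope differences reversed for AZ-5576 minus DMSO in DDIT4 (0.39), MYC (0.39), IER5 (0.43), CISH (0.30) and RPUSD2 (0.57), for JQ1 minus DMSO in ZNF689 (0.0874), HEMGN (0.24), ADO (0.0877) and TUBB3 (−0.0058), and for AZ-5576 minus JQ1 in EGR1 (0.16), IER5 (0.38), DDIT4 (0.39), PPP1R10 (0.32) and BTG1 (0.34).

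TMM scaling, which removes the shared loss of label by its construction, moved the median half-life to 87.2 h in DMSO, 113 h in JQ1 and 127 h in AZ-5576, and turned the DMSO slope of HBG2 (0.13), RPL19 (0.13), RPS2 (0.13), NACA (0.13), COX4I1 (0.13), RPL23A (0.12) and HDGF (0.12). TMM factors of the total counts gave 19.1 h in AZ-5576, and the data without 8 h 5.95 h in DMSO. The rank correlation between loss rate and ratio of total RNA moved without 8 h to −0.0686, −0.254 and −0.311 at 2, 4 and 8 h of AZ-5576 and −0.0897 at 4 h of JQ1. With minus the labelled share at 2 h, which is not a measure of loss, it turned to 0.0940, 0.0979 and 0.140 at 2, 4 and 8 h of AZ-5576. In JQ1 it turned to 0.102 at 4 h and moved to −0.0952 at 2 h. With the loss rate of the other arm it was −0.338 at 4 h of JQ1. Median ratios moved with at least 100 reads to −0.20, −0.58 and −1.45 for AZ-5576 and to −0.30 at 8 h of JQ1, and with fly genes of at least 10 reads to −0.66 at 4 h of AZ-5576 and −0.32 and −0.28 at 2 and 4 h of JQ1. With an estimated correlation 0 gene lists passed in each comparison, against 13, 5 and 11 for total RNA and 1, 1 and 4 for loss rates, and without 8 h 2 lists passed for JQ1 minus DMSO and 1 for AZ-5576 minus JQ1. Among named genes, the difference AZ-5576 against DMSO of total RNA kept its side of the threshold in 497 checks, gained a call in 128 and lost it in 59. Genes with a mean count under 20, CDK9 among them, were left out by the count filter, and only the alternative with no filter tested them.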

Other observations

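Tests chosen only after the result was seen were those on the spike-in scale, on short-lived RNA and on alignment for the rise itself; the tests on gene span, release from the labelling nucleoside, alignment for the relation with span, the 0 h library and the fly RNA were written down before their result was seen, although the fly component itself had been seen.

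Among the 10 genes that rose under AZ-5576, named here after their values were seen, were the small RNA genes RN7SL827P (log2 difference 9.06), U1 (5.02), RNU6-918P (4.98) and RNVU1-25 (3.30). The protein-coding ones were APOA1, an apolipoprotein (4.41), CCNP (4.31) and CCDC80 (2.62), and the others DDX3ILA1 (3.18), PYY2 (2.56) and ENSG00000259001 (2.39). Small nuclear RNAs are not polyadenylated as a rule, and their copies share reads. By gene class, the median ratio to DMSO at 8 h of AZ-5576 was −1.74 for 9823 protein-coding genes, −1.41 for 305 lincRNAs, −1.38 for 317 antisense RNAs and −0.20 for 770 processed pseudogenes.

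Loss rates of labelled RNA had a Spearman's rho across genes of 0.888 between DMSO and JQ1, 0.845 between DMSO and AZ-5576 and 0.848 between JQ1 and AZ-5576. These values share the 0 h library, and simulated counts with unrelated slopes that share it gave 0.0549, 0.0601 and 0.0613. With slopes from each arm's own 2, 4 and 8 h libraries rho was 0.735, 0.683 and 0.647, and genes are not independent replicates. Labelled counts rose past the threshold in 4 genes in DMSO, 10 in JQ1 and 3 in AZ-5576, against 7787, 8007 and 7503 that fell past it.

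A hypothesis was formed for the rise of total RNA over time in DMSO, that long genes recover from 12 h with the labelling nucleoside. A shift of the spike-in scale moves all genes alike. Of 5 equal groups by span, however, the longest had a median slope 0.0948 log2 per hour above the shortest. This gap was 0.0896 to 0.112 with the 0 h or 1 DMSO library left out. A shift of the scale was thus not the whole cause, and its part in the shared rise was left open. With the fly component as a covariate the median slope of the rising genes was 0.176, against 0.159 without it. That does not decide on a library difference shared with the fly RNA. The component itself rose with time in DMSO (−0.404, −0.163, −0.0632 and 0.227 at 0, 2, 4 and 8 h), and the rising genes were chosen by the same slope. Per fly read the slopes were ordered by span, with a rho of 0.323 across 11695 genes, and of 5 equal groups by span those with medians of 1.61 and 128 kb had 214 and 856 genes that rose and 215 and 16 that fell. The slope in JQ1 also went with span (rho 0.243), and that in AZ-5576 did not (rho −0.0516), which is what a release of long genes may give, but a relation with short-lived RNA is not settled (rho 0.214 with the AZ-5576 loss rate, 0.0180 with that of JQ1 and −0.0382 with that of DMSO), and no library of cells without the nucleoside is among the 10 used here. Labelled reads lost in alignment were not the whole cause of the relation with span (rho 0.267 within 5 groups by labelled share), nor was the single 0 h library (rho 0.307 between DMSO 2 and 8 h), but for the rise itself alignment stays open, since the slope from 2 to 8 h went with the labelled share at 0 h (rho 0.380, and 0.402 with 0 h included).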
